A study of Mus musculus with 6 samples.

How the data were processed

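The series holds 6 expression arrays, 3 of ALDH-positive and 3 of ALDH-negative primary mouse ovarian surface epithelium cells. Per the labels' protocols, cells from dissected ovaries of FVB/N mice aged 8 weeks were cultured for 24 hours, stained with ALDEFLUOR with inhibitor-treated and unstained controls, and sorted on a flow cytometer. Total RNA was isolated with the mirVana kit, cDNA was amplified with the Ovation Pico WTA System and labelled with biotin, per the labels' protocols. The amplification from little RNA can lose 5' signal and dim transcripts unevenly between arrays. The series design states 3 independent pools of 10 mice each, hybridization to the Affymetrix Mouse Genome 430 2.0 array, GeneSifter as software and a paired SAM analysis of the fractions.

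The deposited table gives 1 value for each of 45101 probe sets on each array. The deposited values range from 0.035 to 13.06 and were taken as log2 signal from this range; no header states the scale. The summarisation, background correction and normalization used by the authors are not given in the sources used here. Arrays differ in their medians by 0.46 and in their means by 0.04. Because the medians differed by more than 0.2, the limit fixed before the data were examined, the arrays were quantile normalized after removal of 64 control probe sets. Quantile normalization gives each array the same distribution, which pulls the bright genes of the other arrays towards an array with a narrower distribution. Control probe sets were read as deposited. Values near the lower end hold mostly background, so that a fold against such a value depends on the background treatment; detection calls were not used here. All columns of the table were used.

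Probe sets were named from GEO's platform annotation, with symbols updated through the Entrez gene identifier with the RefSeq gene table of the mouse assembly GRCm38.p6. Of 45037 probe sets, 34945 had 1 gene symbol, 932 several and 9160 none; 34741 of those with 1 symbol matched by identifier, and no symbol changed by the update. No gene was named from a probe set with several symbols, and no coordinates were used. Probe sets in the lower 40% by mean over the 6 arrays were removed, at a log2 level of 2.73, which left 27022. Where 1 value per gene was needed, the single-gene probe set of highest mean stood for the gene (12814 genes). Agreement in sign between the probe sets of a gene was to be judged past the threshold, which none passed.

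Fractions were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with the pool as a block and Benjamini-Hochberg adjustment over all probe sets tested at a threshold of 0.05. The pool is the replicate number of the labels, and the pairing comes from the paired analysis of 3 pools in the series design. As a check, the deviations of same-numbered arrays from their group means correlated at 0.34, -0.19 and 0.31 across probe sets in pools 1, 2 and 3. The highest value between arrays of different pools was 0.39 (ALDH-negative of pool 1 with ALDH-positive of pool 2), so the check itself did not single out the pairs. Pool 2 holds the array that stood apart. Since the samples are separate pools of mice, the p-values rest on the spread between pools, which eBayes draws towards a value shared by all probe sets. The SE of a gene with close pool values can therefore exceed its own spread. Bnc1, with pool differences of 5.47, 5.27 and 5.63, had an SE of 0.63. Folds are 2 to the power of the mean log2 difference.

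The test, the samples, the block, the filter, the 24 gene lists and the alternatives were fixed before the data were examined. Lists with at least 5 tested members, 21 of them, were tested with limma's camera (two-sided, preset inter-gene correlation 0.01) with adjustment over the lists, and again with an estimated correlation and with fry. Counts adjusted over the list alone use Benjamini-Hochberg on the p-values of the members of that list. The lists cover aldehyde dehydrogenases, retinoid, Wnt, Notch and Hedgehog signalling, stem and progenitor markers, surface epithelium and mesothelium, other ovarian and neighbouring cell types (granulosa, steroidogenic, stroma, endothelium, leukocytes, smooth muscle, oocytes, erythroid cells, oviduct), cell cycle, p53, stress, interferon and metabolic pathways. Lists share some members, such as Rspo1 and Lgr5.

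Genes named in the text follow a rule fixed with the lists. It takes Aldh1a1, Aldh1a2, Aldh1a3, Aldh1b1, Lgr5, Lef1, Prom1, Cd44 and Krt6b whatever their values. It adds the 10 genes of largest rise and the 10 of largest fall among those past the threshold with the same direction in all pools, filled where fewer pass by the genes of smallest unadjusted p in that direction. It also takes up to 4 tested members of smallest unadjusted p in each list, not all of which are named in the text. Since none passed, the 20 genes of the second part are all of the filled kind. Krt7, Krt8, Krt18, Msln, Wt1, Dsp and Col1a1 were named outside the rule, after their values were seen.

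The 3' and 5' control probe sets of Gapdh and Actb were compared between fractions by an exact permutation over the sign flips of the 3 pairs, which cannot give a p below 0.25. The paired SAM statistic was computed from its definition, with all 8 sign flips of the pools and a median false discovery rate of at most 5%. The scripts were tested on simulated data: 27022 probe sets were drawn around the real pool means and 200 were changed. Their spread was drawn from the distribution that eBayes fitted, equal on all arrays and independent between genes. Limma recovered 4.48% of those changed by a log2 of 4 and 65.2% of those changed by 6, with 4 false calls in all. With no list shifted as a whole and genes drawn independently of each other, camera called 0 lists in these simulated data. This does not measure its false calls among correlated genes. With the surface epithelium list shifted by a log2 of 2, camera called it (adjusted p = 8.33e-17), while with an estimated correlation it did not pass (adjusted p = 0.222). Alternatives were no block, each pool left out, values as deposited, median-centred arrays, no filter and a filter of 60%, an intensity trend, a robust prior, array weights, the mean of a gene's probe sets, the other list tests and SAM. A fit without the ALDH-negative array of pool 2 and without the block was added after seeing the data, and so were the values without pool 2 of single lists.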

Results

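Gene expression was measured in primary ovarian surface epithelium cells of FVB/N mice, the single cell layer that covers the ovary. The cells came from virgin females of 8 weeks and were kept in culture for 24 hours. They were then stained with ALDEFLUOR, a fluorescent substrate of aldehyde dehydrogenases (ALDH), and sorted by flow cytometry into ALDH-positive and ALDH-negative cells. Each of 3 independent pools of 10 mice gave 1 array of each fraction, so that there were 3 ALDH-positive and 3 ALDH-negative samples on 6 Affymetrix Mouse Genome 430 2.0 arrays. The comparison asked which genes distinguish cells with high ALDH activity from the remaining cells of the same pool. Differences below are log2 values of ALDH-positive minus ALDH-negative cells, averaged over the 3 pools, and their number limits the precision.

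The ALDH-negative array of pool 2 stood apart from the others. Its correlation across probe sets with the other arrays was 0.561 to 0.687, while the 5 other arrays correlated at 0.845 to 0.974 with each other. On it, 18S ribosomal RNA read 5.80 at the 3' control probe set, against 8.66 to 12.30 on the other arrays, and Actb, which encodes beta-actin, read 5.03 against 9.56 to 11.04. The spiked bacterial control BioC read 10.02 on this array and 7.87 to 8.73 on the others. Both arrays of pool 3 had a low 5' signal of Gapdh, a glycolytic enzyme, at 6.63 in ALDH-negative and 5.20 in ALDH-positive cells. The 3' minus 5' difference of Gapdh was 0.27 higher in ALDH-positive cells (SD of the 3 pairs 1.37, exact sign-flip permutation p = 0.75, two-sided). That of Actb was -0.27 (SD of the 3 pairs 0.14, exact p = 0.25, the smallest that 3 pairs allow). Where leaving out pool 2 changed the call or the direction of a gene list, the values without it are given. Those fits rest on pools 1 and 3 alone, so their p-values lean heavily on the spread shared by all probe sets.

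**Figure D1:**
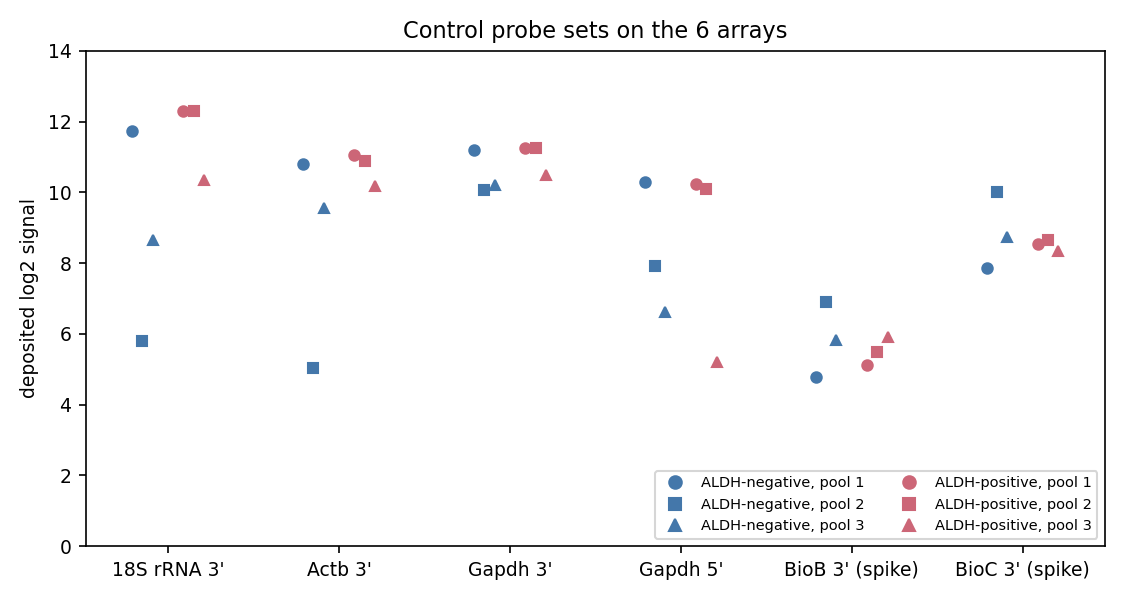
Deposited log2 signal (y axis) of 6 control probe sets (x axis) on each array, with colour for the sorted fraction and symbol for the pool. The ALDH-negative array of pool 2 lies lowest for 18S rRNA (5.80) and Actb (5.03) and highest for the spiked controls BioB (6.90) and BioC (10.02).

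Genes of the surface epithelium and mesothelium had higher signal in ALDH-positive cells. Bnc1, a zinc finger transcription factor of epithelia, was 43.9-fold higher (log2 difference 5.45, SE 0.63, n = 3 pools), with 7.23 ± 0.44 (SD) in ALDH-positive and 1.78 ± 0.26 in ALDH-negative cells. Krt19, an epithelial keratin, was higher by 4.88 (SE 0.74). The membrane glycoprotein Gpm6a was higher by 4.36 (SE 0.65), and the uroplakin Upk1b by 3.92 (SE 0.65). Of the 24 tested members of the list, 22 lay higher in the mean, each of them in all 3 pools. When p-values were adjusted over the list alone, 15 members rose, 1 fell and 8 did not pass, and over all probe sets tested none passed. Without pool 1, 9 rose over the list alone, and Bnc1 passed over all probe sets (limma adjusted p = 0.0456).

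Camera, limma's test of a list against all other genes, called the surface epithelium list higher (adjusted p = 3.26e-24 with a preset correlation of 0.01). With an estimated correlation the adjusted p was 0.425. At the preset correlation camera called 9 lists in all. Under the other labellings that swap fractions within pools it called 9, 8 and 10, so the number of calls does not set the real labelling apart. The list's median difference was 2.78, with 2.998 in pool 1, 2.75 in pool 2 and 1.92 in pool 3. Without pool 2 the median was 2.46, and 17 members rose when adjusted over the list alone, but the list was still not called with an estimated correlation (adjusted p = 0.604). It was called so (adjusted p = 0.0315) in a fit chosen after seeing the data, which left out the ALDH-negative array of pool 2 and the pool block. Among members singled out after their values were seen, the keratins Krt7 (3.61, SE 0.77), Krt18 (3.69, SE 0.85) and Krt8 (2.02, SE 0.68) rose in this adjustment. So did Msln (3.27, SE 0.73), which encodes the mesothelial surface protein mesothelin, and Wt1 (2.07, SE 0.63), a transcription factor of the coelomic epithelium. Dsp, which encodes the desmosomal protein desmoplakin, was the member that fell, by 2.38 (SE 0.84), and its difference without pool 2 was -1.32. Another probe set of Dsp differed by only -0.14.

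**Figure D2:**
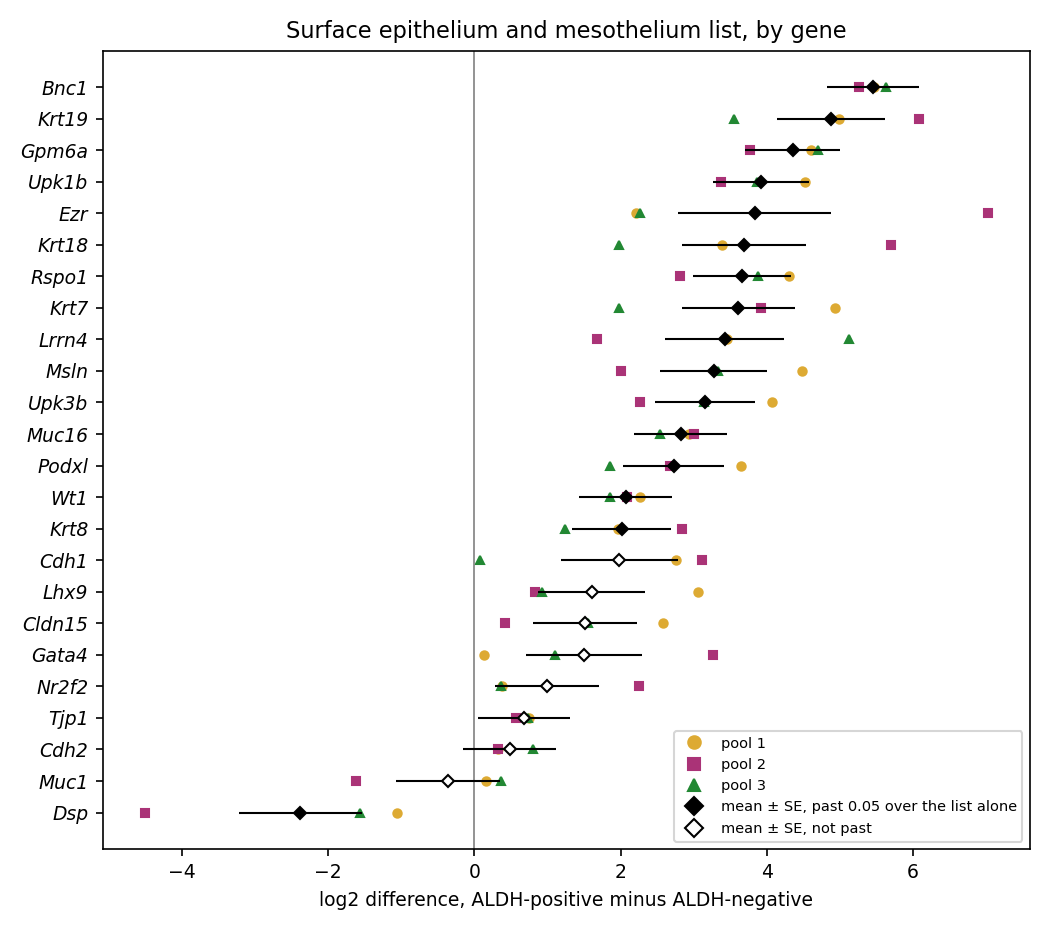
Log2 difference between ALDH-positive and ALDH-negative cells (x axis) for the 24 tested genes of the surface epithelium and mesothelium list (y axis), with coloured symbols for the 3 pools and diamonds for the mean with its SE from limma. Filled diamonds mark the 15 genes higher and the 1 gene lower past 0.05 when adjusted over the list alone; Bnc1 lies at 5.45 and Dsp at -2.38.

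Among the aldehyde dehydrogenases, Aldh1a2, a retinaldehyde dehydrogenase that makes retinoic acid, separated the fractions in each pool. It was 36.1-fold higher in ALDH-positive cells (log2 difference 5.17, SE 0.64), at 7.78 ± 0.17 (SD, n = 3) against 2.61 ± 0.45. The pools gave 5.11, 5.64 and 4.77. Aldh1a1, the related enzyme of the same step, was bright in both fractions of pools 1 and 3, where the differences were 0.75 and 0.61. Its pool 2 difference of 6.92 came with a reading of 2.15 on the ALDH-negative array that stood apart, so its mean of 2.76 had an SE of 1.25. Aldh1a3 differed by -0.62 (SE 0.81) and Aldh1b1 by -0.05 (SE 0.83), both within the spread between pools, and both signs turned without pool 2. The difference of Aldh1b1 was also above 0 in the values as deposited (0.05) and in median-centred arrays (0.21). Aldh1l1, a folate enzyme, differed by -2.02 (SE 0.85), and by -0.93 without pool 2.

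Of the 18 tested aldehyde dehydrogenases, 1 rose when adjusted over the list alone, which was Aldh1a2 (limma adjusted p = 0.00116), and 17 did not pass. The list as a whole had a median of 0.02 and was not called by camera (adjusted p = 0.475). The retinoid signalling list, with a median of 0.40, was not called either (adjusted p = 0.336), and none of its 13 members passed over the list alone. Its members included the retinaldehyde reductase Dhrs3 at 1.49 (SE 0.67) and the transglutaminase Tgm2 at 1.43 (SE 0.71). Of the 13, 8 lay higher and 5 lower. Among the latter Cyp26a1, which degrades retinoic acid, differed by -1.87 (SE 1.08), and by -0.30 without pool 2. Without pool 2 camera called this list higher (median 0.30, adjusted p = 0.0259), with adjusted p = 0.604 at an estimated correlation.

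Lgr5, a receptor for R-spondins and a marker of adult epithelial stem cells, was 9.31-fold higher in ALDH-positive cells (log2 difference 3.22, SE 0.68). It read 4.59 ± 0.93 (SD, n = 3) in ALDH-positive and 1.37 ± 0.19 in ALDH-negative cells, with pool differences of 2.42, 4.06 and 3.18. A second probe set of Lgr5, too dim to be tested, differed by 0.58. The ALDH-negative means of Lgr5, Bnc1 and Aldh1a2 lie below the filter level of 2.73, so that their folds are against background. The same holds for Adgrg2 (1.497), Fas (1.88), Unc45b (2.10), Cdh11 (2.27), Rspo1 (2.45), Cdh1 (2.62) and Thy1 (2.68), named below, by their ALDH-negative means. Lgr5 was the member of the 23 tested stem and progenitor markers that rose when adjusted over the list alone (limma adjusted p = 0.0408); 22 did not pass. The hyaluronan receptor Cd44 differed by 1.61 (SE 0.70). Other tested probe sets of Cd44 gave 0.79 and 1.42, and in pool 3 they read lower in ALDH-positive cells (2.62 against 2.81 and 1.96 against 3.22). The adhesion molecule Alcam differed by 2.30 (SE 0.73), and by 1.23 in the mean of its probe sets. The Wnt effector Lef1 differed by 0.19 (SE 0.77) and the keratin Krt6b by 0.23 (SE 1.02), less than the spread between pools. The only probe set of Prom1 was too dim to be tested. Camera did not call the stem and progenitor list (median 0.19, adjusted p = 0.0969), while without pool 2 it did (median 0.39, adjusted p = 0.00193, and adjusted p = 0.604 with an estimated correlation).

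**Figure D3:**
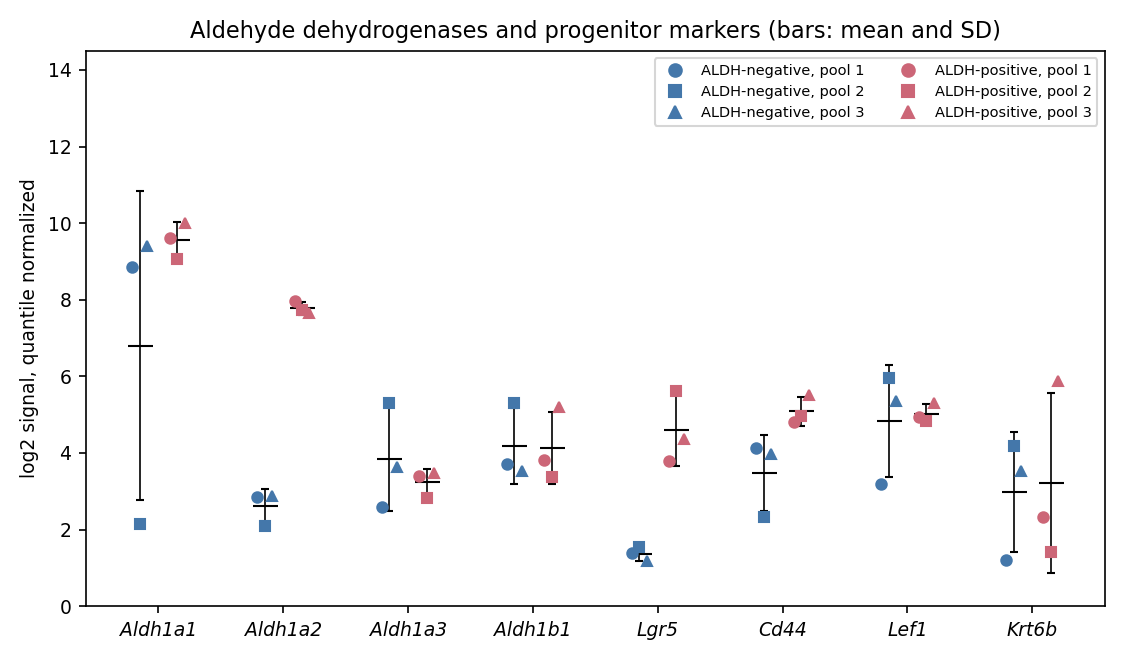
Quantile normalized log2 signal (y axis) of 4 aldehyde dehydrogenases and 4 progenitor markers (x axis) on each array, with colour for the fraction, symbol for the pool, and black bars for the mean and SD of 3 arrays. Aldh1a2 (7.78 against 2.61) and Lgr5 (4.59 against 1.37) separate the fractions without overlap, whereas Aldh1a1 is bright on every array except the ALDH-negative array of pool 2 (2.15).

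In the Wnt signalling list, Rspo1, a secreted ligand of Lgr receptors, was higher by 3.67 (SE 0.67) and also belongs to the surface epithelium list. Rspo1 and Lgr5 were the 2 of 30 tested members that rose when adjusted over the list alone, and 28 did not pass. Camera did not call the list (median 0.25, adjusted p = 0.217). The Notch and Hedgehog list was called lower (median -0.61, adjusted p = 0.018, and adjusted p = 0.651 with an estimated correlation), with the ligand Dhh at -1.36 (SE 0.68) and none of 17 members past the threshold over the list alone. Its medians were 0.08, -2.07 and 0.12 in pools 1 to 3, and without pool 2 the call was lost (median 0.10, adjusted p = 0.822).

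Some genes of stroma and of contractile cells rose in ALDH-positive cells. In the fibroblast and stroma list, 3 of 14 tested members rose when adjusted over the list alone and 11 did not pass. These were the collagen genes Col3a1 (3.90, SE 0.77) and Col6a2 (3.63, SE 0.67) and the fibronectin gene Fn1 (2.61, SE 0.63). Thy1, a surface glycoprotein of fibroblasts, stood at 1.80 (SE 0.65). Camera called the list higher (median 1.12, adjusted p = 2.86e-06, and adjusted p = 0.651 with an estimated correlation). Without pool 2 its median was 0.63 (adjusted p = 7.31e-07, and adjusted p = 0.604 with an estimated correlation), and 5 members rose over the list alone. These were the 3 above, Thy1 and the collagen gene Col1a1 (1.94, SE 0.79, 2.70 without pool 2 and 1.10 without pool 1), the last named after its values were seen. In the smooth muscle and pericyte list, 3 of 9 tested members rose over the list alone, namely the actin gene Acta2 (3.59, SE 0.68), Tagln (2.94, SE 0.67) and Myl9 (2.62, SE 0.71), and 6 did not pass. The median of that list was -0.33 and its mean 0.67, and camera did not call it (direction higher, adjusted p = 0.124). Without pool 2 the median was 0.62 and camera called it (adjusted p = 2.72e-04, and adjusted p = 0.677 with an estimated correlation).

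The epithelial-mesenchymal transition and TGF-beta list was called higher (median 0.74, adjusted p = 4.35e-04, and adjusted p = 0.651 with an estimated correlation). None of its 22 members passed over the list alone; without pool 2, 1 rose, which was Fn1 (limma adjusted p = 0.0213). The ligands Tgfb3 and Tgfb2 differed by 2.21 (SE 0.67) and 2.30 (SE 0.82), and by 2.03 and 1.32 without pool 2. The epithelial cadherin Cdh1, also on the surface epithelium list, was higher as well, by 1.98 (SE 0.80), and by 1.42 without pool 2. Its differences in pools 1 to 3 were 2.76, 3.11 and 0.079. Without pool 2 the median was 0.31 and the list was still called (adjusted p = 0.0319, and adjusted p = 0.604 with an estimated correlation).

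The cell cycle list had a median difference of 1.09. Of its 32 tested members 26 lay higher and 6 lower in the mean, and 21 lay higher in all 3 pools. Camera called the list (adjusted p = 1.87e-07, and adjusted p = 0.651 with an estimated correlation), although none passed when adjusted over the list alone. The replication licensing factor Cdt1 differed by 2.74 (SE 0.98), the helicase subunit Mcm6 by 2.64 (SE 1.16), the kinetochore motor Cenpe by 2.32 (SE 0.86) and the ubiquitin-conjugating enzyme Ube2c by 1.64 (SE 0.72). Without pool 2 these genes differed by 1.32, 0.76, 1.25 and 1.08, and the list median was 0.72 (adjusted p = 6.14e-07, and adjusted p = 0.604 with an estimated correlation). The list of p53 targets and apoptosis was called higher (median 0.49, adjusted p = 0.0342, and adjusted p = 0.651 with an estimated correlation), and without pool 2 that call was lost (median 0.06, adjusted p = 0.159). The death receptor Fas, at 2.25 (SE 0.63), and the junction protein Perp, at 2.59 (SE 0.74), lay higher in all 3 pools, but none of the 17 members passed over the list alone. Without pool 2, 3 members rose when adjusted over the list alone, namely Fas (limma adjusted p = 0.0259), Perp (adjusted p = 0.0267) and the kinase Plk2 (adjusted p = 0.0259), which differed by 1.42 (SE 0.72) over the 3 pools and by 2.06 without pool 2.

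Calls for 3 further lists rested on pool 2. Oxidative phosphorylation had a median of 0.49 (adjusted p = 0.00485), immediate early and heat shock genes 0.85 (adjusted p = 0.0164), and oxidative stress and detoxification 0.76 (adjusted p = 0.0229). Each had adjusted p = 0.651 with an estimated correlation, and no member past the threshold over the list alone. Their pool 2 medians were 1.73, 2.56 and 2.25. Without that pool the medians were 0.08, -0.02 and -0.12, and camera called none of the 3 (adjusted p = 0.615, 0.822 and 0.486). The cytochrome oxidase gene Cox4i1 shows the pattern, with 7.38 in pool 2 against 0.0024 and 1.20 in pools 1 and 3. Gpx1, a glutathione peroxidase, gave 5.91 against -0.15 and 1.45, and the transcription factor Klf6 gave 7.34 against 0.70 and 0.40. Fosl1, an AP-1 subunit, was positive in each pool (mean 2.16, SE 0.78, and 1.39 without pool 2). The heat shock gene Hspa1b was negative in each pool (mean -1.52, SE 0.73, and -0.98 without pool 2). Of the 22 immediate early and heat shock genes tested, 16 lay higher and 6 lower in the mean.

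Markers of the other cell types that a preparation from the ovary can hold were examined in the same way. Steroidogenic genes were bright in both fractions of pool 1, where Cyp11a1, the enzyme that cleaves the cholesterol side chain, read 11.44 in ALDH-negative and 10.69 in ALDH-positive cells. Hsd3b1, which makes progesterone, read 10.42 and 10.09 there, and Fdx1, the electron donor of Cyp11a1, read 11.15 and 10.69. In pool 3 Cyp11a1 read 8.42 in ALDH-negative and 7.28 in ALDH-positive cells, while Hsd3b1 read 10.11 and 9.67 and Fdx1 read 11 and 10.68. In pool 2 Cyp11a1 read 4.09 on the ALDH-negative array and 10.68 on the ALDH-positive one. Its mean difference was 1.57 (SE 1.45), and -0.94 without pool 2. The theca, interstitial and luteal list was not called over all pools (median 0.68, adjusted p = 0.232). It had medians of -0.73 and -0.70 in pools 1 and 3 against 3.21 in pool 2, and without pool 2 camera called it lower (median -0.67, adjusted p = 5.59e-04, and adjusted p = 0.604 with an estimated correlation). With array weights it was also called lower, but without pool 1 and without pool 3, where pool 2 remained, it was called higher. Granulosa markers were not called (median 0.49, adjusted p = 0.217; without pool 2 -0.08, adjusted p = 0.446). Of these, the inhibin subunit Inhbb stood at 1.497 (SE 0.71), and Inha at 1.23 (SE 0.96) overall but -0.08 without pool 2. A list that is not called can still be bright in both fractions. In pools 1 and 3 Inha read 9.95 and 7.78 in ALDH-negative and 9.06 and 8.52 in ALDH-positive cells. The subunit Inhba read 9.22 and 9.20, and 9.40 and 8.85. The estrogen receptor Esr2 was dimmer, at 4.02 and 4.36, and 3.99 and 4.06. Fshr and Cyp19a1 were not among the tested members.

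Neither endothelial (median -0.46, adjusted p = 0.409) nor leukocyte markers (median -0.29, adjusted p = 0.242) were called. Both negative medians came from pool 2 (-1.71 and -1.13); without it they were 0.17 and 0.43 and not called either (adjusted p = 0.482 for both). The vascular receptor Kdr stood at 1.44 (SE 0.72), the endothelial coreceptor Eng at -1.16 (SE 0.65) and the lysozyme gene Lyz1 at -1.33 (SE 0.64). Too few members were bright enough for a test of oocyte (2 tested, median -0.42), erythroid (2 tested, median -0.31) and oviduct epithelium markers (4 tested, median 0.05). Without pool 2 these medians were 0.32, -0.31 and 0.33. The oviduct and epididymal secretory gene Wfdc2 was at 1.33 (SE 0.69). Interferon response genes were not called (median 0.04, adjusted p = 0.948), with the oligoadenylate synthetase-like gene Oasl2 at 1.82 (SE 0.66). Fatty acid oxidation and lipid storage genes were not called (median 0.27, adjusted p = 0.7), with Acadvl, a mitochondrial acyl-CoA dehydrogenase, at 1.33 (SE 0.80), and at 0.52 without pool 2. The median of that list without pool 2 was -0.12 (adjusted p = 0.482). The cholesterol synthesis list was not called over all pools (median 0.33, adjusted p = 0.7) but was called lower without pool 2 (median -0.57, adjusted p = 5.59e-04, and adjusted p = 0.604 with an estimated correlation). Its member Mvd, an enzyme of the mevalonate pathway, stood at -1.14 (SE 0.66) and was negative in all 3 pools. Srebf2 stood at 1.99 (SE 1.09) and Sqle at 1.68 (SE 1.17), and at 0.30 and -0.20 without pool 2. Of the 17 tested members of that list 9 lay higher and 8 lower in the mean.

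**Figure D4:**
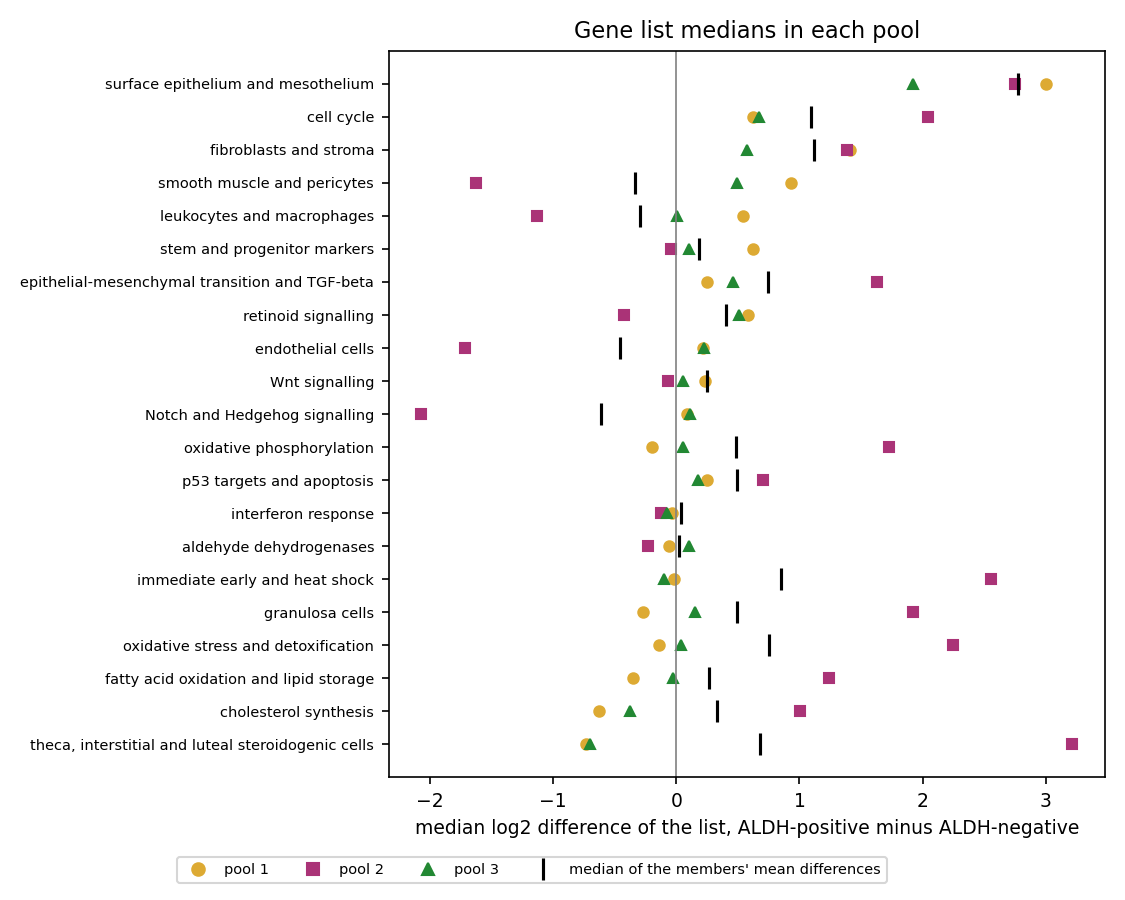
Median log2 difference between ALDH-positive and ALDH-negative cells (x axis) of each of the 21 tested gene lists (y axis), with symbols for the 3 pools and a bar for the median of the members' mean differences. The surface epithelium list lies at 2.998, 2.75 and 1.92 in the 3 pools, while the theca, interstitial and luteal list lies at -0.73 and -0.70 in pools 1 and 3 and at 3.21 in pool 2.

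Over all genes, the largest differences by strength of evidence were again towards ALDH-positive cells. Beside Bnc1, Aldh1a2, Gpm6a, Krt19 and Upk1b, the 10 highest genes were the kinase Stk26 (4.89, SE 0.74), the cadherin Cdh11 (4.23, SE 0.67), the adhesion protein Flrt2 (4.23, SE 0.76), the adhesion receptor Adgrg2 (4.17, SE 0.65) and the myosin chaperone Unc45b (3.91, SE 0.63). Limma called 0 of 27022 probe sets after adjustment over all of them (smallest adjusted p = 0.765); 661 had an unadjusted p under 0.05, 552 of them higher and 109 lower, where chance gives 1351. This skew depended on pool 2 and on the weights: 619 were higher and 613 lower without pool 2, and 3223 and 3406 with array weights. Without the ALDH-negative array of pool 2 and the pool block, 388 were higher and 244 lower. The series names a paired SAM statistic, but the settings of the submitters' run are not given in the sources used here. SAM run on the same values over the 8 sign flips of the 3 pools called 51 probe sets at a median false discovery rate of at most 5%. All 51 were higher in ALDH-positive cells. They represent 40 genes, including each of the 10 highest genes above and 8 genes of the surface epithelium list. SAM and limma used the same pool differences, so this overlap is no separate support. The 8 sign flips include the real labelling and its mirror image, so the false discovery rate is coarse. Of Flrt2, SAM called other probe sets (3.54 and 2.37) than the one above. Limma with array weights called 2953 probe sets, so that the choice of error model is left open by these counts.

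Towards ALDH-negative cells, no probe set passed in the limma fit with equal weights or in SAM. Without pool 1 limma called 4 probe sets higher and 3 lower, and with array weights 1478 higher and 1475 lower. The genes with the strongest evidence were the protocadherin Pcdh7 (-2.61, SE 0.65), the lipid droplet protein Plin5 (-2.31, SE 0.68), the sulfotransferase Chst15 (-2.19, SE 0.67), E130308A19Rik (-3.03, SE 0.95) and the histone demethylase Kdm7a (-2.54, SE 0.80). The kinase Frk (-2.30), the natriuretic peptide receptor Npr3 (-2.55), Spag1 (-2.17), the inositol kinase Ipmk (-2.62) and the F-box gene Fbxl20 (-2.09) followed. Each of these 10 genes was lower in ALDH-positive cells in all 3 pools. These are values of 1 probe set per gene. In the mean of all probe sets of a gene Pcdh7 was at -0.064, E130308A19Rik at -0.51, Ipmk at -0.82, Frk at -0.90, Fbxl20 at -1.02, Kdm7a at -1.03 and Plin5 at -1.62. Without pool 2 Kdm7a was at -1.62 and Npr3 at -1.60. Of all tested probe sets, 22.3% had the same sign in the 3 pools, against 25% by chance. Simulated data were drawn with the spread that eBayes fitted, equal on all arrays. In them limma recovered 0 of 67 probe sets changed by a log2 of 2, 3 of 67 changed by 4 and 43 of 66 changed by 6. Differences of the size seen here mostly could not pass in those data. The real arrays were uneven, with array weights of 0.158 for pool 2 and 4.87 for pool 3, so these shares may not carry over.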

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

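The count of probe sets past limma's threshold was 0 in the analysis with the pool as a block and stayed 0 without the replicate block, in values as deposited, in median-centred arrays, without a filter, with the stricter filter, with an intensity trend and with a robust prior. Leaving out 1 pool gave 0 to 7 probe sets, 0 to 4 higher and 0 to 3 lower; the 7 came without pool 1. Array weights gave 2953, of which 1478 were higher and 1475 lower, and paired SAM gave 51, all 51 higher. Camera called 9 lists, and 0 with an estimated correlation and 0 with fry; without the replicate block it called 10, and in the other alternatives 7 to 10. A simulated list shifted by a log2 of 2 was not called with an estimated correlation either. For the surface epithelium list fry gave adjusted p = 0.104 for a shift in 1 direction and adjusted p = 0.0412 for change in either direction. Leaving out pool 2 also gave 9 lists, but only 4 of them were called in the same direction as before, and 4 were shared as well without the ALDH-negative array of pool 2 (chosen after seeing the data). The surface epithelium members that rose over the list alone numbered 15, and 9 to 17 when 1 pool was left out, with 9 without pool 1. Median-centring moved the median of all probe sets from -0.04 to 0.22. The pseudocount alternatives were not run, since the values are already on a log scale.

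Of 937 comparisons of a named gene with an alternative, 863 kept their direction and their side of the threshold, 53 passed only in the alternative and 21 turned direction. Cdh1, Srebf2, Sqle, Hspa1b, Inhba and Esr2 were not among the genes compared. When 1 pool was left out, the difference of Lef1 ranged from -0.59 to 0.84, Krt6b from -0.83 to 1.73, Aldh1a3 from -1.33 to 0.31, Aldh1b1 from -0.91 to 0.89, Fdx1 from -0.38 to 2.22, Cyp11a1 from -0.94 to 2.93, Hsd3b1 from -0.39 to 1.29 and Inha from -0.078 to 2.29. Without the ALDH-negative array of pool 2, Aldh1a3 was at 0.11, Aldh1b1 at 0.51, Fdx1 at -0.40, Cyp11a1 at -0.38, Hsd3b1 at -0.27 and Inha at -0.22. With array weights, Aldh1b1 was at 1.25, Fdx1 at -0.22, Cyp11a1 at -0.87 and Hsd3b1 at -0.34. Aldh1b1 was at 0.048 as deposited and at 0.21 in median-centred arrays. When 1 pool was left out, list medians ranged from -0.99 to 0.10 for Notch and Hedgehog signalling, from -0.017 to 1.37 for immediate early and heat shock genes, from -0.12 to 0.98 for oxidative stress and from 0.078 to 0.94 for oxidative phosphorylation. The oxidative stress list was at -0.028 with array weights and at -0.079 without the ALDH-negative array of pool 2, where oxidative phosphorylation was at 0.045. The 3' minus 5' difference of Gapdh ranged from -0.45, without pool 3, to 0.91. Without the ALDH-negative array alone the immediate early and heat shock median stayed positive, at 0.20. The cause of these turns was not tested. Signal over background limits the dim genes, whose differences are bounded by the background level.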

Other observations

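The tests of the arrays and of the surface epithelium list were chosen after those results were seen; the tests of the splits and of the array weights were set before theirs.

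Beyond the genes named by the rule, the 51 probe sets that SAM called include the following genes, chosen after their values were seen and not tested as a group. They are the crosslinking enzymes Lox (2.64) and Loxl1 (3.14), the latent TGF-beta binding protein Ltbp2 (2.71) and Ccdc80 (3.27). The caveolar gene Cavin2 was higher by 4.17 and the insulin-like growth factor binding protein Igfbp3 by 3.21, and the transcription factors Nfib (2.98) and Maf (2.83) were called with 2 probe sets each. A second probe set of Lhx9, a gonadal transcription factor, was called at 4.47, where the one that stood for the gene gave 1.60. The second read 1.24, 1.37 and 1.87 in ALDH-negative cells, below the filter level of 2.73, so that 4.47 is against background.

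The ALDH-negative array of pool 2 correlated less with the other 5 arrays. Its 5 spiked BioB and BioC controls exceeded the highest other array by at least 0.92, while its 18S and beta-actin controls lay below every other array by at least 1.77, as little sample cDNA would give. Gapdh goes against a general lack of it: its 3' probe set read 10.07 against 10.22 to 11.25 on the other arrays, and its 5' probe set 7.92, above both arrays of pool 3 (6.63 and 5.20). Little sample cDNA therefore stays open. The surface epithelium median of pool 2 was 2.75, in the direction of the other pools, but does not decide on a swap of its 2 fractions. Other lists rose there too, with medians of 3.21 (theca, interstitial and luteal) and 2.56 (immediate early and heat shock). Levels on the ALDH-positive array of pool 2 argue against a swap. Of the genes fixed beforehand, Aldh1a2 and Lgr5 differed most without pool 2. On this array Aldh1a2 read 7.73, against 7.97 and 7.64 on the ALDH-positive arrays of pools 1 and 3. The ALDH-negative arrays of those pools read 2.86 and 2.87. Lgr5 read 5.61, against 3.79 and 4.36 on those ALDH-positive and 1.38 and 1.18 on those ALDH-negative arrays. Bnc1, Gpm6a, Krt19 and Upk1b, picked by their p over all pools, read 6.74 to 9.10 there. On those ALDH-negative arrays they read 1.92 to 3.90. A general property of ALDH-negative cells is argued against. The mean correlation of the ALDH-negative array of pool 2 with the other ALDH-negative arrays exceeded that with the ALDH-positive ones by 0.011. On the ALDH-negative array of pool 2, 3002 probe sets read above 6, against 6004 to 8690 on the other arrays. The ALDH-positive array of pool 2 correlated at 0.974 with that of pool 1 and at 0.860 with that of pool 3. This argues against a difference shared by all cells of pool 2. A difference confined to its ALDH-negative cells was not tested apart from a fault of the array and stays open.

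The surface epithelium list was higher in ALDH-positive cells. The array of pool 2 alone is argued against by the median of 2.46 without that pool. Loss of 5' signal in 1 fraction stays open: the list median was at least 1.92 in each pool, but the 3' minus 5' gap between fractions turned sign only for Gapdh, in pool 2 (-1.01 against 0.10 and 1.71), and for Actb it was -0.19, -0.44 and -0.20. The median did not follow the size of the gaps. It was largest in pool 1 (2.998), where both gaps were smallest in size, and smallest in pool 3 (1.92), where the Gapdh gap was largest. More granulosa and steroidogenic cells among ALDH-negative cells could lower the share of surface epithelium there. Without pool 2 camera called the steroidogenic list lower in ALDH-positive cells (adjusted p = 5.59e-04, and adjusted p = 0.604 with an estimated correlation) but not the granulosa list (median -0.082). The steroidogenic list was called higher without pool 1 and without pool 3. Pool 2 remained in both fits, with a list median of 3.21 and Cyp11a1 at 4.09 on the ALDH-negative array that stood apart. Those calls therefore do not speak against such cells. The granulosa list, called in neither direction without pool 2, does not decide either. A larger share of such cells thus cannot be told apart from a difference within the surface epithelium. No gate against such cells other than the ALDEFLUOR sort is named in the labels.

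Array weights turned 0 calls into 2953, with a weight of 4.87 for pool 3 and 0.158 for pool 2. If such weights made the fit too liberal, the other 3 labellings that swap fractions within pools should give many calls too, and the highest of them gave 126. The labelling with 126 calls is one whose weights did not converge. Another of them, with a weight of 6.01 for pool 1, gave 69 calls, so weights resting on 1 pool did not always give so many calls. None of the 3 rested mostly on pool 3 (weights 2.34, 1.13 and 0.97), where the real calls mostly rest and 5' Gapdh was low. Weights resting on pool 3 were thus not tested, and 3 other labellings are few, so that weights as the cause stay open.

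The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 0 probe sets and the highest other 11341. Every split reaches a count of 0, so this comparison could not decide anything. Both splits with 11341 calls part only the arrays of pool 2, so that with the pool as a block they are the same fit. The difference between the arrays of pool 2 decides that count, which points to a structure of the samples. The same holds for other splits that part a single pool: they come in pairs of the same fit. For gene lists the real split called 9 and the highest other 10, with 5 splits, the real one included, giving at least 9. Among the 4 splits that part every pair, 3 called at least 9 lists, the real one included. The others called 9, 8 and 10 lists and 0 probe sets, so the number of called lists did not set the real split apart.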
